A study of Mus musculus with 21 samples.

How the data were processed

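The values analysed were the estimated counts per gene that the authors deposited, rounded here to whole counts. Of the values above 0 in a library, between 28.2% and 45.4% were not whole numbers. According to the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7, aligned with STAR 2.7.10a to the mouse genome GRCm39 and counted with featureCounts. The tool that made fractional counts is not given in the sources used here. Libraries were made from sorted cells with a low-input kit that amplifies by PCR. No molecular identifiers are named, so intervals and count floors cover counting error only. The labels call the samples biological replicates, and p values measure the spread between samples.

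The table had 57180 genes, 46.7% of them at 0 in all libraries, and 18867 passed the filter of edgeR by group and were tested. No row for GFP or Cre was in the table (0). All 21 libraries entered a single edgeR quasi-likelihood fit (TMM scaling, robust) with 6 group means, from which 11 comparisons were taken. P values were adjusted by Benjamini and Hochberg within each comparison, with 0.05 as the limit and no fold minimum. Adjusted p values of genes come from edgeR, and those of lists from camera in limma on log2 CPM with a preset correlation of 0.01, adjusted over the 30 lists of a comparison. Each list was also tested with a correlation estimated from the data. CPM are TMM-normalised and given as mean and SD. The SE of a log2 fold change is its absolute value over the square root of the F statistic of edgeR. It was not fitted separately. A fold was not given where a group had 1 to 3 counts. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

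The comparisons, the 30 lists, the naming rule and the first set of other fits were fixed before the data were examined. The lists were homeostatic microglia, microglia over bone-marrow-derived brain macrophages, bone-marrow-derived brain macrophages over microglia, border macrophages, disease-associated microglia, type I interferon response, MHC class I presentation, MHC class II presentation, inflammatory cytokines and NF-kB, complement and Fc receptors, lipid and cholesterol handling, lysosome and phagocytosis, cell cycle, TGF-beta signalling, purinergic and neuron-sensing receptors, glycolysis and hypoxia, oxidative phosphorylation, immediate early and heat shock genes, ribosomal proteins, mitochondrially encoded transcripts, Y-linked genes and X inactivation, and 9 lists of other cells (neurons, astrocytes, oligodendrocytes and precursors, endothelium and mural cells, neutrophils, T and NK cells, B cells, blood monocytes and dendritic cells, red cells and choroid plexus). Lists were written from general knowledge and members absent from the table were left out. By the naming rule, genes could be named if they were Csf1r or Cx3cr1, among the 6 largest called changes per direction with an average log2 CPM of at least 4 and no overlap of libraries, or members of a list. Which of these genes were printed was decided after the other fits had been run, so the share of printed calls that held in other fits is not a share of all calls.

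The first set of other fits held DESeq2, limma-voom with quality weights, RLE scaling, no low-count filter, a fit of only the groups compared, the replicate number as a block, the code in the library names as a block, the 2 MLC seizure libraries coded 11b left out or summed with the library of the same code, and each library left out in turn. GC-content correction, leaving out the 3 libraries with the fewest genes at equal depth, and thinning to the smallest total were added after the libraries had been examined. Simulated data with the same groups and 200 changed genes were used to test the pipeline. All changed genes had an average log2 CPM of at least 4, so recovery among less abundant genes was not measured. In MLC against MG after saline edgeR recovered 2.99% of 2-fold, 29.9% of 4-fold and 60.6% of 8-fold changes. After seizure it recovered 1.49%, 53.7% and 78.8%. Of 221 simulated calls of DESeq2 in the saline comparison 121 were false, so its larger counts were not preferred. Limma-voom had 5 false among 62 simulated calls there, and edgeR 0 among 62. The simulation thus gives no such reason to set aside the larger counts of limma-voom.

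Within groups, log CPM correlated between libraries from 0.909 to 0.960 after saline and from 0.785 to 0.879 after seizure. The shared spread may therefore be too wide for saline and too narrow for seizure comparisons. GC content was known for 95.4% of tested genes.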

Results

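Gene expression was measured by RNA-seq in 21 libraries of cells sorted from mouse brain, each labelled a biological replicate. Microglia are the resident macrophages of the brain. The libraries held transplanted microglia (MG), transplanted monocytes that had become microglia-like cells (MLC), and microglia of mice without a transplant (NoTx). Both kinds of transplanted cells had the genotype Osb-GFP, and the NoTx cells were heterozygous for CX3CR1-CreER with floxed CSF1R alleles. Genotype and transplantation therefore cannot be told apart in any comparison of MG or MLC with NoTx. Cells were taken after saline (3 MG, 3 MLC and 2 NoTx libraries) or 5 days after seizures brought on by kainic acid, a glutamate receptor agonist (4 MG, 6 MLC and 3 NoTx libraries). All seizure libraries were labelled batch 1 and all saline libraries batch 2, so treatment and batch cannot be told apart. Estimated gene counts per library ran from 36.5 M to 50.3 M after saline and from 6.57 M to 73.8 M after seizure. Between 17893 and 21988 genes were detected per saline library and between 13074 and 17591 per seizure library. With every library thinned to the smallest total, these ranges were 15390 to 17839 and 12337 to 15468 genes.

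Csf1r and Cx3cr1, the genes named in the NoTx genotype, were read in every library. Csf1r, the receptor on which microglia depend for survival, had a mean of 7818 ± 3446 CPM (normalised to library size; SD, n = 3) in MG after saline, 3759 ± 3419 (n = 3) in MLC and 1835 ± 1542 (n = 2) in NoTx. After seizure the Csf1r levels were 2536 ± 1279 CPM (n = 4), 924 ± 599 (n = 6) and 3993 ± 3995 (n = 3). Cx3cr1, the fractalkine receptor, had 9325 ± 1408, 4216 ± 3235 and 1877 ± 1260 CPM in MG, MLC and NoTx after saline, and 3629 ± 1328, 1437 ± 804 and 2641 ± 1887 CPM after seizure. Within groups, Csf1r varied with the GC-content trend of the libraries, with Pearson's r = 0.876 and Spearman's rho = 0.939 over the 21 libraries (permutation p = 1.0e-05 for each, the smallest possible). Xist, expressed from the inactive X chromosome of females, exceeded 50 CPM in 3 of 3 MG saline and 4 of 4 MG seizure libraries. The summed Y-linked transcripts exceeded 50 CPM in 2 of those 3 and in 4 of those 4. All 9 MLC libraries and both NoTx saline libraries held Y-linked transcripts without Xist. The letter F or M in the names of seizure libraries matched these transcripts in 3 of 3 NoTx, 3 of 6 MLC and 0 of 4 MG libraries. Xist was therefore not read as a difference between kinds of cells. It exceeded 50 CPM in every MG library and in no MLC library, so sex and kind of cells cannot be told apart in MLC against MG. Nor can they in MG against NoTx after saline. Xist exceeded 50 CPM in 2 of 3 NoTx seizure libraries, so sex was unbalanced in the comparisons that hold these libraries too. In MLC against MG 288 of 299 calls after saline and 1074 of 1109 after seizure were autosomal or unplaced. This does not exclude an effect of sex on them.

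**Figure D1:**
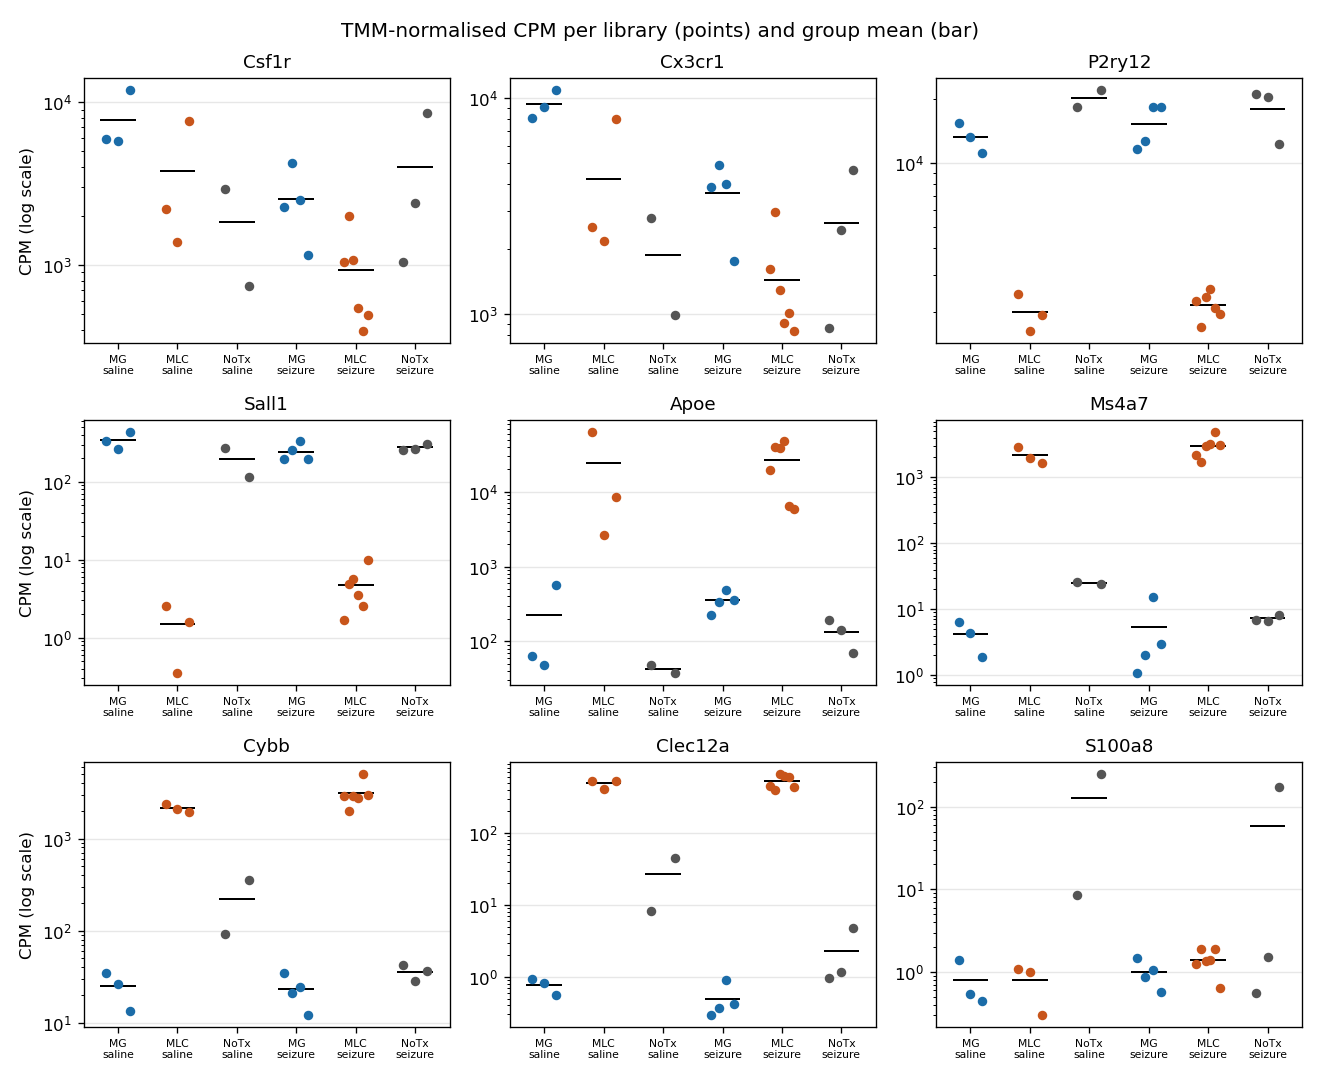
TMM-normalised CPM (log scale) of 9 genes, 1 point per library and a bar at each group mean, for MG, MLC and NoTx after saline and after seizure. Mean Csf1r ran from 924 to 7818 CPM, and mean Sall1 from 1.49 to 342 CPM.

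The first comparison asked how transplanted cells of monocyte origin differed from transplanted microglia in the brain at homeostasis (MLC against MG, saline, n = 3 in each). Transcripts that set microglia apart from other macrophages were low in MLC. Sall1, a transcription factor of microglial identity, had 1.49 ± 1.10 CPM in MLC and 342 ± 83.3 in MG (log2 fold change -7.83, SE 0.73, adjusted p = 4.7e-07), and its relative Sall3 had a log2 fold change of -9.02 (SE 0.95). P2ry12, an ADP receptor that steers microglial processes, was present in MLC at 2003 ± 408 CPM against 13289 ± 2134 in MG (log2 fold change -2.73, SE 0.29, adjusted p = 1.9e-06). In the opposite direction, Ms4a7, a membrane protein of monocyte-derived brain macrophages, had 2163 ± 626 CPM in MLC and 4.20 ± 2.23 in MG (adjusted p = 5.0e-07). Apoe, the carrier of lipids between brain cells, had 24522 ± 32871 CPM in MLC and 224 ± 291 in MG (log2 fold change 6.78, SE 1.18, adjusted p = 0.0014).

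Of 18867 genes tested with edgeR, 147 were higher and 152 lower in MLC at an adjusted p under 0.05. Largest among the abundant genes that passed, with no overlap of libraries, were the uroplakin Upk1b (log2 fold change -8.56, SE 0.58), Csmd3 (-8.85, SE 0.73), the small heat shock protein Hspb3 (-9.13, SE 0.87) and Mlph (-8.43, SE 1.45), an adaptor of vesicle transport, on the low side. On the high side stood Spic (9.80, SE 1.05), a transcription factor of iron-recycling macrophages, the growth factor Gdf3 (9.50, SE 1.12), the inhibitory lectin receptor Clec12a (9.31, SE 0.75), the interferon-inducible Mndal (9.12, SE 0.77) and Ifi203 (9.12, SE 1.04), and Ms4a14 (9.05, SE 0.66). Csf1r and Cx3cr1 had log2 fold changes of -1.06 (SE 0.73) and -1.15 (SE 0.58) and did not pass (adjusted p = 0.98 and 0.68).

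Among 21 tested members of the homeostatic microglia list, 14 were lower in MLC (17 adjusted over the list alone). The list fell against other genes (median log2 fold change -2.28, camera adjusted p = 7.7e-35, or 2.9e-05 with an estimated correlation). Sparc, a matricellular protein (-4.04, SE 0.36), and Ecscr, a surface protein shared with endothelium (-5.65, SE 0.55), were among them, while Tmem119 (-1.75, SE 0.88) did not pass. Of 26 genes written as higher in microglia than in bone-marrow-derived brain macrophages, 15 were lower in MLC (20 adjusted over the list alone; adjusted p = 1.3e-37, or 2.0e-07 with an estimated correlation). Of 40 genes written as higher in bone-marrow-derived brain macrophages, 21 were higher in MLC (29 higher and 1 lower adjusted over the list alone; adjusted p = 3.3e-37, or 7.1e-05 with an estimated correlation). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, was one of them, at 2129 ± 227 CPM in MLC against 25.0 ± 10.9 in MG (log2 fold change 6.41, SE 0.55).

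Of 20 border macrophage genes, 7 were higher in MLC (8 adjusted over the list alone; adjusted p = 4.7e-15, or 3.9e-06 with an estimated correlation). They held the chemokine Pf4 (log2 fold change 8.63, SE 0.77), the mannose receptor Mrc1 (5.73, SE 0.83) and the chemokine Ccl8 (7.67, SE 1.15). All 41 tested genes of the type I interferon response had a positive log2 fold change (median 1.61), of which 3 passed (9 adjusted over the list alone; adjusted p = 4.7e-15, or 0.03 with an estimated correlation). They held Bst2, which tethers budding viruses to the cell (2.33, SE 0.33), and the DNA sensor Ifi207 (4.53, SE 0.77). Of 35 lipid and cholesterol genes, 5 were higher (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.00048, or 0.0063 with an estimated correlation). Msr1 (5.18, SE 0.91) and Cd36 (5.56, SE 1.10), scavenger receptors for modified lipoproteins, were among these. Cd36 lost its call without MG replicate 3 (adjusted p = 0.057).

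Of 13 genes of MHC class II presentation, 6 were higher in MLC (8 adjusted over the list alone; adjusted p = 2.7e-06, or 0.16 with an estimated correlation). H2-Ab1, a class II chain, had 15998 ± 12845 CPM in MLC and 279 ± 52.7 in MG (log2 fold change 5.84, SE 1.19), and this call was lost without any of MG replicates 1, 2 and 3 (adjusted p = 0.057, 0.057 and 0.067). The MHC class I list had 18 of 21 positive log2 fold changes and 0 called genes (adjusted p = 0.01, or 0.57 with an estimated correlation). Of 30 purinergic and neuron-sensing receptors, 3 were lower (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.01, or 0.30 with an estimated correlation). The adenosine receptor Adora3 had a log2 fold change of -4.96 (SE 0.86).

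Several lists split or stayed near 0. Of 27 genes of disease-associated microglia, 4 were higher and 3 lower (7 and 3 adjusted over the list alone; adjusted p = 0.28). Apoe was on the high side, and the tetraspanin Cd9 (-1.96, SE 0.32) and the protease Ctsl (-2.30, SE 0.33) were on the low side. Of 36 inflammatory and NF-kB genes, 3 were higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.051). The chemokines Ccl7 (5.98, SE 0.94), Ccl12 (3.48, SE 0.60) and Cxcl16 (2.87, SE 0.49) were the higher ones. The lysosome list had 4 higher and 3 lower of 39 (5 and 5 adjusted over the list alone; adjusted p = 0.49, with a median of -0.32 and a mean of 0.14). The complement and Fc receptor list had 1 higher and 1 lower of 20 (1 and 2 adjusted over the list alone; adjusted p = 0.43). Adjusted p values were 0.59 for cell cycle, 0.49 for TGF-beta signalling, 0.11 for glycolysis and hypoxia, 0.74 for oxidative phosphorylation, 0.49 for immediate early and heat shock genes, 0.49 for ribosomal proteins and 0.28 for mitochondrially encoded transcripts. Lists of other cells had adjusted p values of 0.74 for neurons, 0.48 for astrocytes, 0.96 for oligodendrocytes and precursors, 0.47 for endothelium and mural cells, 0.49 for neutrophils, 0.43 for T and NK cells, 0.78 for B cells, 0.96 for blood monocytes and dendritic cells and 0.41 for red cells and choroid plexus, and sex-linked transcripts had 0.70. The sex-linked list sets Xist and Tsix beside Y-linked genes, with 2 lower of 6 (4 higher and 2 lower adjusted over the list alone). Changes in opposite directions cancel in its test, so 0.70 does not speak against a difference in sex. The tests of astrocytes and blood monocytes pointed down while their medians were 0.30 and 0.09, and that of oligodendrocytes up with a mean of -0.18. The astrocyte list held 1 lower gene, the glutamate transporter Slc1a3 (-5.75, SE 0.73).

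Leaving out 1 library brought the 299 calls to 180 without MG replicate 1, 181 without MG replicate 2, 180 without MG replicate 3, 196 without MLC replicate 1 and 180 without MLC replicate 2. DESeq2 called 660 and limma-voom 1698 genes.

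**Figure D2:**
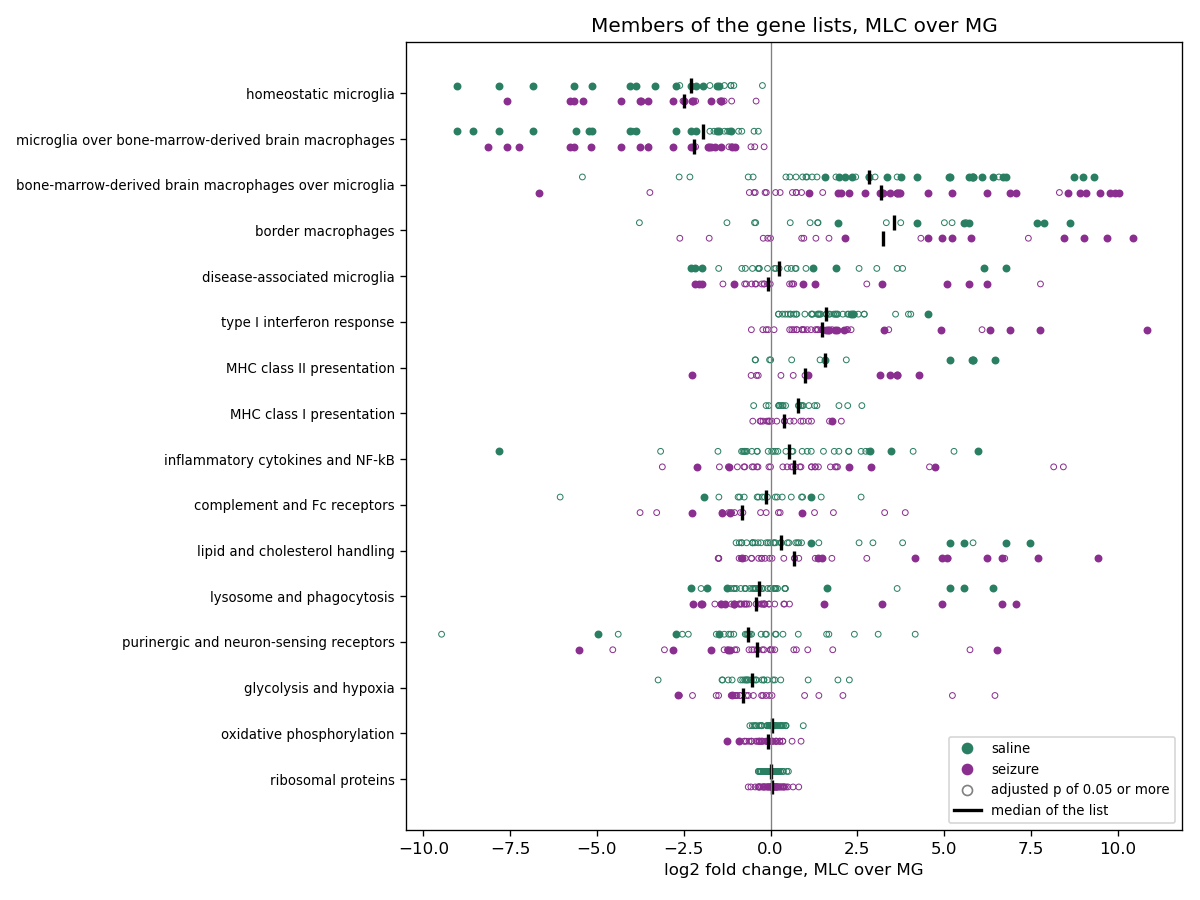
Log2 fold change of MLC over MG for each tested member of 16 gene lists after saline (green) and after seizure (purple), with filled points for genes with an adjusted p under 0.05 and black bars at list medians. The median of the homeostatic microglia list was -2.28 after saline and -2.49 after seizure.

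The same comparison was made among cells taken 5 days after kainic acid (MLC against MG, seizure, n = 6 and 4). The labels call all 6 MLC libraries biological replicates, but the names of replicates 3 and 6 repeat the code of replicates 2 and 4 with 11b added, and whether they came from the same animals is not given in the sources used here. If they did, n is 4 and p values are too small. Calls numbered 828 without these libraries and 839 with each summed with the library of the same code. Sall1 was again low in MLC, at 4.71 ± 2.97 against 243 ± 63.2 CPM (log2 fold change -5.67, SE 0.48, adjusted p = 4.2e-08), and P2ry12 had 2162 ± 310 against 15223 ± 3574 CPM (-2.82, SE 0.21, adjusted p = 7.0e-09). Clec12a had 526 ± 110 CPM in MLC and 0.496 ± 0.275 in MG (log2 fold change 9.93, SE 0.67, adjusted p = 2.5e-09). Apoe reached 26388 ± 18105 CPM in MLC against 353 ± 107 in MG (6.22, SE 0.98, adjusted p = 0.00022).

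With edgeR, 474 genes were higher and 635 lower in MLC after seizure. The largest abundant ones on the low side were Zfp697 (log2 fold change -8.68, SE 1.11), Fscn1 (-8.14, SE 0.62), which bundles actin, Hspb3 (-8.05, SE 0.61), the integrin Itgb3 (-7.82, SE 0.89), Tmem204 (-7.77, SE 0.67) and B3galt5 (-7.76, SE 1.07). On the high side, Nlrc4, an inflammasome sensor of bacterial proteins, and Vnn3 had log2 fold changes of 10.65 (SE 1.15) and 10.13 (SE 1.27). Itgal, the alpha chain of the leukocyte integrin LFA-1, had 42.5 ± 18.9 CPM in MLC against 2 counts over the 4 MG libraries. Iqgap2 (54.5 ± 17.1 CPM) had 1 count in MG, and Serpina3g (47.4 ± 49.0 CPM) had 3. Csf1r (-1.46, SE 0.57) and Cx3cr1 (-1.34, SE 0.45) did not pass, with adjusted p = 0.12 and 0.08.

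The homeostatic list held 15 lower genes of 21 (21 adjusted over the list alone; adjusted p = 1.1e-26, or 0.00014 with an estimated correlation), while Tmem119 (-2.16, SE 0.67, adjusted p = 0.059) did not pass. Of 26 genes written as higher in microglia than in bone-marrow-derived macrophages, 19 were lower (23 adjusted over the list alone; adjusted p = 1.1e-26, or 2.1e-06 with an estimated correlation). Of the 40 genes written the other way, 25 were higher and 1 lower (29 and 3 adjusted over the list alone; adjusted p = 1.1e-26, or 0.00046 with an estimated correlation). The NAD-consuming enzyme Cd38 (9.49, SE 0.69) and Cybb (7.06, SE 0.48) were among the higher ones. Of 20 border macrophage genes, 9 were higher (13 adjusted over the list alone; adjusted p = 5.5e-10, or 5.7e-05 with an estimated correlation), with Mrc1 at 842 ± 180 CPM in MLC and 22.4 ± 19.9 in MG. In the type I interferon list 12 of 41 were higher (20 adjusted over the list alone; adjusted p = 4.4e-16, or 0.024 with an estimated correlation), with the DNA sensor Ifi211 at 124 ± 58.9 CPM in MLC and 1.61 ± 2.92 in MG (6.33, SE 1.06). Of 35 lipid genes, 9 were higher and 1 lower (11 and 2 adjusted over the list alone; adjusted p = 0.00088, or 0.008 with an estimated correlation), with Msr1 (6.67, SE 0.84) and Cd36 (4.93, SE 0.90) among the higher.

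The inflammatory list had 3 higher and 2 lower genes of 36 (6 and 5 adjusted over the list alone; adjusted p = 0.036, or 0.074 with an estimated correlation). Ccl7 (4.75, SE 0.75) and Ccl12 (2.89, SE 0.49) were higher, and the lipopolysaccharide co-receptor Cd14 (-1.19, SE 0.30) was lower. MHC class II had 6 higher and 1 lower of 13 (6 and 1 adjusted over the list alone; adjusted p = 0.021, or 0.60 with an estimated correlation). Glycolysis and hypoxia genes were lower as a list (2 lower of 26, and 1 higher and 7 lower adjusted over the list alone; adjusted p = 0.022, or 0.60 with an estimated correlation). Pdk1, a kinase that turns pyruvate away from mitochondria, had a log2 fold change of -2.67 (SE 0.40). Purinergic receptors were lower (1 higher and 5 lower of 30, and 1 and 7 adjusted over the list alone; adjusted p = 0.036, or 0.50 with an estimated correlation), with Adora3 at 8.66 ± 8.22 CPM in MLC and 390 ± 109 in MG. Mitochondrially encoded transcripts were higher as a list (15 of 15 positive, 1 called and 4 adjusted over the list alone; adjusted p = 0.0062, or 0.60 with an estimated correlation). They made up 1.55% to 2.51% of counts in MLC replicates 4 to 6, of which replicate 5 is a low-complexity library, and 0.661% to 1.05% in MLC replicates 1 to 3, against 0.482% to 1.03% in MG. Disease-associated genes split again, with 6 higher and 4 lower of 27 (7 and 4 adjusted over the list alone; adjusted p = 0.35, with a median of -0.06 and a mean of 0.86). The lists of neurons, astrocytes, neutrophils and blood monocytes had adjusted p = 0.25, 0.22, 0.74 and 0.93.

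DESeq2 called 1518 genes higher and 929 lower, and 617 genes passed without MG replicates 3 and 4 and MLC replicate 5, whose libraries had the fewest genes with 10 or more counts at equal depth. RLE scaling moved the median log2 fold change of all genes by 0.17 and gave 545 higher and 477 lower genes, 53.3% higher in place of 42.7%.

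Genes called in MLC against MG after saline were nearly all called in the same direction after seizure, in libraries not shared with the first comparison. Of 147 higher genes 143 were again higher and of 152 lower genes 145 were again lower, where independent lists would share 3.69 and 5.12. Both comparisons came from 1 fit with a shared spread for each gene, which favours calling the same genes. The expected numbers take account neither of this nor of abundance. Which treatment had more calls depended on the fit. With only the groups compared there were 872 after saline and 502 after seizure, and limma-voom called 1698 and 1064. Xist set MG apart from MLC in both treatments, so the shared calls are not separated from sex. Across 6856 genes with an average log2 CPM of at least 4, the log2 fold changes correlated with Pearson's r = 0.876 and Spearman's rho = 0.728. This is a correlation across genes, which are not independent replicates, and over all 18867 genes r was 0.427. Whether the difference between MLC and MG changed with treatment was tested as an interaction. With edgeR 0 genes passed, 1036 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 143 and 8. Cd38 had 78.6 ± 22.3 CPM in MLC and 2.20 ± 0.958 in MG after saline, and 85.2 and 0.0948 ± 0.0758 after seizure (log2 fold change of the difference 4.34, SE 0.79, adjusted p = 0.28), and Csf1r (-0.40, SE 0.92) and Cx3cr1 (-0.19, SE 0.73) did not pass. In simulated data with the same libraries, 34.8% of 8-fold and 5.97% of 4-fold interactions were recovered among genes with an average log2 CPM of at least 4.

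**Figure D3:**
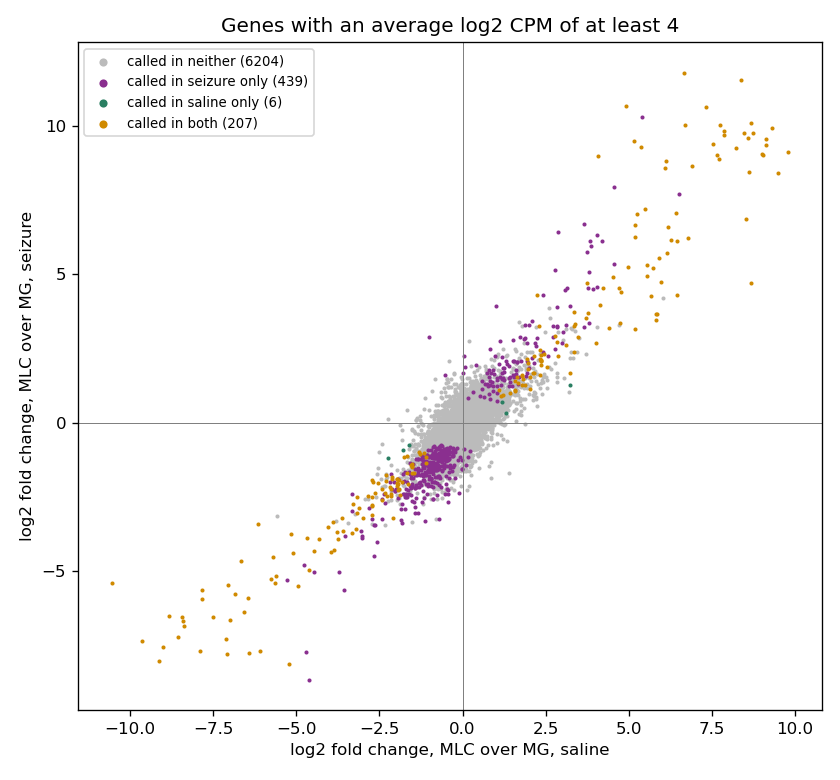
Log2 fold change of MLC over MG after saline (x) against that after seizure (y), 1 point per gene with an average log2 CPM of at least 4, coloured by where the gene passed an adjusted p of 0.05. Of 6856 genes plotted, 207 passed in both, 6 in saline alone and 439 in seizure alone in the fit of all 6 groups.

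Transplanted and endogenous microglia were compared next (MG against NoTx). They differed in genotype too, so transplantation and genotype cannot be told apart here. After saline (n = 3 and 2), Sall1 had 342 ± 83.3 CPM in MG and 193 ± 113 in NoTx (log2 fold change 0.82, SE 0.62) and P2ry12 13289 ± 2134 against 20041 ± 2574 (-0.59, SE 0.30), and neither passed. A few genes written for macrophages of bone marrow origin (2 of 40) or the brain borders (1 of 20) were called lower in MG. Clec12a had 0.769 ± 0.193 CPM in MG against 8.20 and 44.9 CPM in the 2 NoTx libraries (log2 fold change -5.10, SE 0.65, adjusted p = 0.00077). Mndal, which is in none of the lists, had a log2 fold change of -5.49 (SE 0.68). Pf4 had 0.522 ± 0.126 CPM in MG and 8.93 and 10.3 CPM in NoTx (-4.19, SE 0.67, adjusted p = 0.011). In the same NoTx libraries Camp, an antimicrobial peptide of neutrophils, had 9.61 and 280 CPM and did not pass (adjusted p = 0.064). Csf1r (2.09, SE 0.88) and Cx3cr1 (2.31, SE 0.70) did not pass either.

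With edgeR 1 gene was higher and 9 were lower in MG. Xist was the higher one, and beside Clec12a, Mndal, Pf4 and Cybb (-3.15, SE 0.49) the lower ones were Ifi203 (-5.41, SE 0.91), the signalling regulator Rgs18 (-6.33, SE 1.09), the detoxifying enzyme Mgst1 (-6.37, SE 1.13) and the predicted genes Gm21188 and Gm36161, these last chosen after their values were seen. The border macrophage list was lower in MG (1 of 20 genes, 6 adjusted over the list alone; adjusted p = 1.6e-18, or 1.5e-06 with an estimated correlation). So was the list of blood monocytes and dendritic cells (0 of 21 called, 10 adjusted over the list alone; adjusted p = 1.9e-18, or 1.6e-05 with an estimated correlation). The neutrophil list was lower too (0 of 10 called, 7 adjusted over the list alone; adjusted p = 2.9e-13, or 0.038 with an estimated correlation), as was the list of bone-marrow-derived macrophages (2 of 40, and 1 higher and 7 lower adjusted over the list alone; adjusted p = 6.9e-07, or 0.10 with an estimated correlation). The MHC class I list was higher in MG (0 of 21 called, 19 positive, 3 adjusted over the list alone; adjusted p = 2.8e-07, or 0.10 with an estimated correlation), with H2-D1 at 1216 ± 667 CPM in MG and 146 ± 47.5 in NoTx (3.06, SE 0.88, adjusted p = 0.67). The lists of oxidative phosphorylation (adjusted p = 0.0012), cell cycle (0.029), endothelium (0.014) and B cells (0.046) were lower. Those of glycolysis (0.0025), neurons (0.0083), the lysosome (0.014), purinergic receptors (0.019), interferon response (0.039), inflammation (0.039), astrocytes (0.04) and complement (0.041) were higher. With an estimated correlation these lists had adjusted p = 0.52, 0.36, 0.073, 0.36, 0.36, 0.41, 0.52, 0.36, 0.52, 0.10, 0.52 and 0.44, in that order. Cybb, a lysosome member that was lower, was the only called gene among their members. The number of calls was 1 without NoTx replicate 2, 18 without NoTx replicate 1, and 6, 2 and 2 without MG replicates 1, 2 and 3. Without either NoTx replicate that arm is 1 library. The spread then comes from the other groups, so these 2 counts are no test of it. DESeq2 called 104 and limma-voom 439 genes. With only the groups compared 2 genes passed, of which 1 was among the 10 first called, and with the replicate block 3 passed.

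After seizure (MG against NoTx, n = 4 and 3), Sall1 (243 ± 63.2 CPM in MG and 276 ± 28.8 in NoTx) and P2ry12 (15223 ± 3574 and 17918 ± 4915) again did not pass, nor did Csf1r (-0.65, SE 0.67) and Cx3cr1 (0.46, SE 0.54). The fungal pattern receptor Clec7a was higher in MG, at 77.6 ± 36.5 CPM against 14.9 ± 7.49 in NoTx (log2 fold change 2.39, SE 0.44, adjusted p = 0.037). The lymphocyte receptor Ly9 (2.53, SE 0.46) and the interferon-inducible GTPase Iigp1c (5.42, SE 0.93) were also higher, and Pnp, an enzyme of purine salvage, was lower (-1.86, SE 0.30, adjusted p = 0.013). These 4 calls were lost without NoTx replicate 2, with adjusted p = 0.17, 0.15, 0.11 and 0.053. With edgeR 9 genes were higher and 5 lower. With only the groups compared 0 genes passed, with the replicate block 0 and at equal depth 6. The type I interferon list was higher in MG (35 of 41 positive, 1 adjusted over the list alone; adjusted p = 3.0e-05, or 0.42 with an estimated correlation), as was MHC class I (17 of 21 positive, 3 adjusted over the list alone; adjusted p = 0.0086, or 0.59 with an estimated correlation). The neutrophil list was lower (6 of 10 adjusted over the list alone; adjusted p = 0.0041, or 0.52 with an estimated correlation), as was the astrocyte list (adjusted p = 0.049, or 0.68 with an estimated correlation). The neutrophil transcripts lay in NoTx replicate 3, with S100a8 at 171 CPM against 0.553 and 1.52 in NoTx replicates 1 and 2. The list of sex-linked transcripts had adjusted p = 0.0046, or 0.24 with an estimated correlation. No member of these lists passed over all genes. The number of calls was 38 without MG replicate 2, 5 without MG replicate 3, 8 without NoTx replicate 2 and 9 without NoTx replicate 3. The balance of directions was not stable, with 5 higher and 19 lower with limma-voom, 373 and 254 with DESeq2, 3 and 5 without NoTx replicate 2, and 28 and 1 without the low-complexity libraries.

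The interaction of MG against NoTx with treatment gave 2 genes with edgeR, the unannotated transcripts 4930523C07Rik (log2 fold change of the difference 9.47, SE 1.40, adjusted p = 0.014) and Gm37900 (8.03, SE 1.31, adjusted p = 0.032), both chosen after their values were seen. 4930523C07Rik had 3.82 ± 1.42 CPM in MG and 15.5 ± 8.94 in NoTx after saline, and 8.65 ± 0.756 and 0.0433 ± 0.0377 after seizure. The border macrophage list (adjusted p = 7.0e-09, or 0.00015 with an estimated correlation) and the blood monocyte list (adjusted p = 5.4e-07, or 0.0037 with an estimated correlation) were lower in MG than in NoTx after saline by more than after seizure, with no member called. The number of calls was 0 without MG saline replicate 2, MG saline replicate 3, NoTx saline replicate 2, NoTx seizure replicate 1 or NoTx seizure replicate 3, 1 without MG saline replicate 1, 4 without NoTx seizure replicate 2 and 7 without MG seizure replicate 2. Without NoTx saline replicate 2 that group is 1 library. With only the groups compared, with the replicate block and at equal depth 0 genes passed. Neither Csf1r (-2.75, SE 1.09) nor Cx3cr1 (-1.85, SE 0.85) passed.

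MLC were also set against endogenous microglia, from which they differed in genotype too. After saline (MLC against NoTx, n = 3 and 2), Upk1b had 0.306 CPM in MLC and 504 ± 74.2 in NoTx (log2 fold change -10.68, SE 0.63, adjusted p = 7.1e-10). Sall1 (-7.01, SE 0.72), Sparc (-4.59, SE 0.38) and P2ry12 (-3.32, SE 0.31) were low in MLC, and Csmd3, Hspb3 and Sall3 had log2 fold changes of -9.48 (SE 0.76), -9.46 (SE 0.89) and -9.02 (SE 0.97). Ms4a7 had 2163 ± 626 CPM in MLC and 25.1 ± 1.45 in NoTx (6.43, SE 0.93, adjusted p = 0.0003), and Gdf3 (8.47, SE 1.30), Ms4a14 (6.83, SE 0.71) and the chemokine receptor Ccr1 (4.97, SE 0.74) were high. With edgeR 84 genes were higher and 153 lower, and Csf1r (1.03, SE 0.84) and Cx3cr1 (1.17, SE 0.67) did not pass. Of the 40 genes of bone-marrow-derived macrophages 16 were higher and 1 lower (26 and 3 adjusted over the list alone; adjusted p = 5.6e-21, or 0.0016 with an estimated correlation), and of 21 homeostatic genes 10 were lower (15 adjusted over the list alone; adjusted p = 6.5e-23, or 0.00032 with an estimated correlation). The list of microglia over bone-marrow-derived macrophages had 15 lower of 26 (19 adjusted over the list alone; adjusted p = 6.2e-31, or 7.6e-07 with an estimated correlation).

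Interferon genes were higher in MLC than in NoTx (5 of 41, 14 adjusted over the list alone; adjusted p = 1.2e-17, or 0.014 with an estimated correlation), Bst2 among them (2.52, SE 0.39). So were genes of MHC class I (3 of 21, 9 adjusted over the list alone; adjusted p = 2.2e-10, or 0.029 with an estimated correlation) and lipid handling (4 of 35, 6 higher and 1 lower adjusted over the list alone; adjusted p = 0.00064, or 0.0074 with an estimated correlation). Inflammatory genes had 4 higher and 1 lower of 36 (7 and 1 adjusted over the list alone; adjusted p = 0.00036, or 0.0053 with an estimated correlation), with Ccl12 (3.83, SE 0.73) and Cxcl16 (3.93, SE 0.61) higher. The lists of neutrophils (4 of 10, 6 adjusted over the list alone; adjusted p = 4.0e-10, or 0.032 with an estimated correlation) and blood monocytes (2 of 21, 8 adjusted over the list alone; adjusted p = 6.7e-12, or 0.00027 with an estimated correlation) were lower. The border macrophage list did not pass (5 of 20 higher, 7 higher and 3 lower adjusted over the list alone; adjusted p = 0.36). Endothelial and mural genes were lower (1 of 10, 2 adjusted over the list alone; adjusted p = 0.0051, or 0.02 with an estimated correlation), as was the list of oxidative phosphorylation (0 of 46 called; adjusted p = 0.025, or 0.77 with an estimated correlation). MHC class II (2 of 13, 8 adjusted over the list alone; adjusted p = 2.2e-05, or 0.18 with an estimated correlation), disease-associated microglia (4 higher and 3 lower of 27; adjusted p = 0.012, or 0.39 with an estimated correlation) and neurons (0 of 17 called; adjusted p = 0.014, or 0.44 with an estimated correlation) were higher as lists. Camp, high in NoTx replicate 2, had a log2 fold change of -9.97 (SE 1.79) and was not called without that library. With 1 of the 2 NoTx libraries left out the spread comes from the other groups, so such fits are no test of NoTx. The 237 calls went to 80 without NoTx replicate 2, 104 without NoTx replicate 1 and 147, 143 and 146 without MLC replicates 1, 2 and 3. DESeq2 called 348 genes higher and 313 lower, and limma-voom 662 and 889.

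After seizure (MLC against NoTx, n = 6 and 3), Upk1b had 1.53 ± 0.867 CPM in MLC and 598 ± 216 in NoTx (log2 fold change -8.62, SE 0.42, adjusted p = 1.3e-11), and Sall1 (-5.85, SE 0.50), P2ry12 (-3.05, SE 0.23) and Fscn1 (-8.14, SE 0.63) were low. Cybb had 3081 ± 991 CPM against 35.8 ± 7.11 (6.43, SE 0.53, adjusted p = 3.8e-08). The lectin receptor Clec4n (9.31, SE 0.91), Spic (9.48, SE 1.03), the thrombin receptor Thbd (10.07, SE 1.28) and Cd93 (9.20, SE 1.58), a receptor of phagocytes, were among the largest high in MLC. Csf1r had a log2 fold change of -2.11 (SE 0.60, adjusted p = 0.039), lost without NoTx replicate 3 (adjusted p = 0.43) and under 16 other alternatives. With edgeR 481 genes were higher and 681 lower. Interferon genes were higher (23 of 41, 30 adjusted over the list alone; adjusted p = 2.2e-25, or 0.0046 with an estimated correlation), with the nucleic acid sensor Zbp1 at 27.3 ± 21.3 CPM in MLC and 0.215 ± 0.234 in NoTx (7.09, SE 1.06). Inflammatory genes had 8 higher and 1 lower of 36 (12 and 4 adjusted over the list alone; adjusted p = 0.0034, or 0.014 with an estimated correlation), with Ccl7 (8.83, SE 1.06) and Ccl12 (4.47, SE 0.61) higher. Of the homeostatic list 17 of 21 were lower (20 adjusted over the list alone; adjusted p = 1.2e-25, or 0.00018 with an estimated correlation), and of the 40 bone-marrow-derived macrophage genes 29 were higher and 1 lower (33 and 3 adjusted over the list alone; adjusted p = 1.1e-30, or 0.0002 with an estimated correlation). The neutrophil list was lower (7 of 10; adjusted p = 0.0047, or 0.41 with an estimated correlation), with its transcripts in NoTx replicate 3, where Camp had 95.3 CPM against 1.04 and 1.03 in NoTx replicates 1 and 2. The list of microglia over bone-marrow-derived macrophages was lower (21 of 26; adjusted p = 7.3e-28, or 1.6e-06 with an estimated correlation). Higher lists were border macrophages (8 of 20; adjusted p = 4.5e-08, or 0.00018 with an estimated correlation), lipid handling (11 of 35; adjusted p = 0.00064, or 0.0061 with an estimated correlation), MHC class I (5 of 21; adjusted p = 0.00028, or 0.32 with an estimated correlation), MHC class II (6 of 13; adjusted p = 0.0014, or 0.35 with an estimated correlation), disease-associated microglia (7 higher and 4 lower of 27; adjusted p = 0.034, or 0.41 with an estimated correlation) and mitochondrially encoded transcripts (15 of 15 positive, 0 called; adjusted p = 0.0053, or 0.41 with an estimated correlation). The last were 1.55% to 2.51% of counts in MLC replicates 4 to 6, 0.661% to 1.05% in MLC replicates 1 to 3 and 0.522% to 0.943% in NoTx. Glycolysis (4 of 26; adjusted p = 0.0021, or 0.35 with an estimated correlation) and purinergic receptors (1 higher and 5 lower of 30; adjusted p = 0.023, or 0.35 with an estimated correlation) were lower. Calls numbered 830 without MLC replicates 3 and 6 and 857 with these summed with the library of the same code. The number of calls was 707 without NoTx replicate 2 and 726 without NoTx replicate 3, and DESeq2 called 1778 genes higher and 970 lower.

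Seizure and saline libraries of each kind of cell were set side by side, with treatment and batch the same split, so no value here is read as an effect of seizure. In MG (n = 4 and 3), 7 genes were lower in the seizure libraries and 0 higher with edgeR, with 2226 at an unadjusted p under 0.05 and DESeq2 and limma-voom at 274 and 260. Cd38 had 0.0948 ± 0.0758 against 2.20 ± 0.958 CPM (log2 fold change -4.22, SE 0.61, adjusted p = 0.0059), and Saa3, an acute phase protein chosen after its values were seen, 0.0749 ± 0.0533 against 29.4 ± 17.2 (-8.51, SE 1.48, adjusted p = 0.037). Neither Csf1r (-1.62, SE 0.68) nor Cx3cr1 (-1.36, SE 0.54) passed. Oxidative phosphorylation (40 of 46 positive, adjusted p = 2.4e-11, or 0.75 with an estimated correlation) and ribosomal protein genes (49 of 56 positive, adjusted p = 7.4e-06, or 0.99 with an estimated correlation) were higher as lists, with no member called. The number of calls was 0 without MG seizure replicate 4, 3 without replicate 3 and 13 without replicate 1, 0 without the low-complexity libraries, and 1, 2 and 2 without MG saline replicates 1, 2 and 3. With only the groups compared and at equal depth 0 genes passed.

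In MLC (seizure and saline, n = 6 and 3) 0 genes passed with edgeR, 2236 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 130 and 103. Upk1b (2.30, SE 0.44, adjusted p = 0.25), Fscn1 (-3.10, SE 0.58, adjusted p = 0.25), Csf1r (-2.02, SE 0.60) and Cx3cr1 (-1.55, SE 0.48) did not pass. Mitochondrially encoded transcripts (14 of 15 positive, adjusted p = 2.4e-06, or 0.70 with an estimated correlation), oxidative phosphorylation (adjusted p = 8.3e-07, or 0.70 with an estimated correlation), ribosomal protein (adjusted p = 3.7e-06, or 0.72 with an estimated correlation) and immediate early genes (adjusted p = 0.0068, or 0.26 with an estimated correlation) were higher and glycolysis genes (adjusted p = 0.02, or 0.70 with an estimated correlation) lower in seizure libraries as lists. Mitochondrial transcripts were 1.55% to 2.51% of counts in MLC seizure replicates 4 to 6, against 0.661% to 1.05% in replicates 1 to 3 and 0.612% to 0.842% after saline. In NoTx (n = 3 and 2) 1 gene, Xist, was higher and 19 were lower, among them Cd38 (-4.94, SE 0.69, adjusted p = 0.0025), Mndal (-5.11, SE 0.68, adjusted p = 0.0025), Clec12a (-3.52, SE 0.61) and Cybb (-2.63, SE 0.49), while Csf1r (1.12, SE 0.84) and Cx3cr1 (0.49, SE 0.65) did not pass. Xist exceeded 50 CPM in 2 of 3 seizure and 0 of 2 saline libraries of NoTx, so sex was unbalanced between them. The border macrophage list (1 of 20 lower, 10 adjusted over the list alone; adjusted p = 4.5e-14, or 8.9e-06 with an estimated correlation) and the blood monocyte list (0 of 21 lower, 5 adjusted over the list alone; adjusted p = 1.7e-12, or 0.00017 with an estimated correlation) were lower in seizure libraries, beside the high Camp of NoTx saline replicate 2. Also lower in seizure libraries were the lists of bone-marrow-derived macrophages (3 of 40 called, adjusted p = 8.2e-10), neutrophils (0.00092), interferon response (0.021) and endothelium (0.045), with 0.052, 0.54, 0.66 and 0.23 with an estimated correlation. Higher as lists were ribosomal proteins (adjusted p = 0.00092), oxidative phosphorylation (0.013), lysosome (0.014), glycolysis (0.016), astrocytes (0.019), microglia over bone-marrow-derived macrophages (0.032), homeostatic microglia (0.044), mitochondrially encoded transcripts (0.044) and MHC class I (0.045), with 0.66, 0.66, 0.66, 0.66, 0.66, 0.24, 0.66, 0.66 and 0.66 with an estimated correlation. Cybb, lower and in the lysosome list, was the only called gene among these. The number of NoTx calls was 5 without NoTx saline replicate 2, which leaves 1 saline library, and 4, 11 and 10 without NoTx seizure replicates 1, 2 and 3, and DESeq2 and limma-voom called 218 and 90 genes.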

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

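The tests of causes in this section were chosen after the results had been seen, as were the splits within sets, GC-content correction, thinning and leaving out low-complexity libraries.

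Csf1r, Tmem119 and Cx3cr1 varied within groups far more than P2ry12. Across 21 libraries their deviations from group means rose with the GC-content trend of the library, with Pearson's r = 0.876 and Spearman's rho = 0.939 for Csf1r, 0.906 and 0.961 for Tmem119, and 0.804 and 0.906 for Cx3cr1 (permutation p of at most 8.0e-05, 5 genes tested). Without the 2 libraries farthest out, MLC seizure 5 and MG seizure 4, r for Csf1r was 0.945. AT-rich Gpr34 ran the other way over all 21 libraries with r = -0.859, -0.734 without those 2, and -0.233 in saline and -0.955 in seizure libraries. Correction for GC content left a median of 82.0% of the within-group SD of the 3 genes, from 73.0% for Tmem119 to 96.4% for Cx3cr1. It shifts a gene only by the trend at that gene's own GC content. The SD left therefore cannot tell whether the trend of the libraries is the whole cause. A loss of homeostatic expression in some libraries stays open. The other 18 homeostatic members went both ways (median correlation with the 3 genes 0.112), with 5 above 0.5, among them Golm1 (0.895), and 7 negative, among them Gpr34 (-0.715). RNA quality and amplification were not tested.

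Clec12a, Mndal, Pf4, Cybb and 5 other genes were lower in MG than in NoTx after saline. If all Apoe and Ms4a7 of NoTx had been carried over from MLC, at most 1.80% of an MLC level could have been. Of the 9 genes 7 in NoTx replicate 1 and 9 in replicate 2 exceeded what this carry-over of MLC RNA or reads allows. Ifi203 and Clec12a in replicate 1 did not. The 9 genes were called for being higher in these same libraries than in MG, which favours this outcome. Carry-over therefore stays open. The blood monocyte list, which held none of the called genes (adjusted p = 1.6e-05 with an estimated correlation), and the border macrophage list without its called gene (adjusted p = 4.3e-06) were lower in MG, consistent with cells of both kinds in the NoTx sort. The 2 lists share members with other lists, no sort gate is named, and NoTx replicate 2 held most of the monocyte and neutrophil transcripts, so a true difference of NoTx microglia stays open.

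Calls were recounted after moving libraries between the groups compared. In MLC against MG after saline 1 of 10 splits, the real one, reached 299 calls (highest other 0), and there are too few splits for a test. In MLC against MG after seizure 1 of 100 drawn splits, the real one, reached 1109 (highest other 574). In MLC against NoTx after seizure 1 of 84, again the real one, reached 1162 (highest other 607). Chance is thus unlikely in both if the MLC libraries coded 11b are replicates of their own. These shares are the smallest that the splits can give and were not adjusted over comparisons. Splits with as many calls were common for MG against NoTx after seizure (7 of 35 splits reached 14, highest other 95) and seizure against saline in MG (3 of 35 reached 7, highest other 14), so chance stays open there. For seizure against saline in MLC (84 of 84 splits) and the interaction of MLC and MG (100 of 100) the real count was 0, which any split reaches, so the splits test nothing there. The interaction split with most calls, 392, put all MG seizure libraries in 1 arm with MLC 5 and 6, and so holds the difference between MLC and MG itself.

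Seizure library names hold a set number, 1 for MG 1 and 2, MLC 1 to 3 and NoTx 1 and 2, and 2 for the rest. The split with 571 calls for seizure against saline in MLC placed MLC seizure 4 to 6, all of set 2, against MLC seizure 1 to 3 and the MLC saline libraries. This, and the 95 calls in MG against NoTx after seizure, where MG 1 and 2 were parted from MG 3 and 4, point to a structure among the libraries. In a fit with the sets apart, 194 genes passed between the sets in MG and 1 in MLC, with 3214 and 3074 at an unadjusted p under 0.05. NoTx has 1 library in set 2, too few for this. MLC of set 2 also had more mitochondrial counts (1.55% to 2.51% against 0.661% to 1.05%) and lower GC-content trends, and MG of set 2 were low-complexity libraries, so what the structure is stays open. Among splits that keep the sets balanced, 1 of 100 reached 1109 in MLC against MG after seizure (highest other 67) and 1 of 40 reached 1162 in MLC against NoTx (highest other 82). Both were the real split, so chance within sets is unlikely in both under the same condition on 11b. For MG against NoTx 3 of 18 reached 14 (highest other 34), too few splits for a test. With the library code, which holds the set number, as a block, 1571, 1184 and 9 genes passed in these 3 comparisons.

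Some single libraries lay apart from their group, 6 of 83 values tested among the genes and totals printed, where 4.15 would by chance. Itgb3 had 4.96 CPM in MG seizure 3 against 31.0 to 35.6 in the other MG seizure libraries. Cd14 had 168 CPM in MLC seizure 5 against 648 to 887. Fscn1 had 0 CPM in MLC seizure 2 against 0.135 to 0.259. Iqgap2 had 0.0265 CPM in MG seizure 3 and Serpina3g 0.0953 CPM in MG seizure 4, with 0 in the other MG seizure libraries. Where the others tie at 0 any count sets a library apart, and Fscn1 was near 0 in every MLC seizure library. These values lie at the count floor and say little about the libraries. The total of MLC seizure 3 was 37.5 M counts against 6.57 M to 14.9 M.

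The difference between MG and NoTx was not the same after saline and after seizure for 4930523C07Rik (log2 fold change of the difference 9.47) and Gm37900 (8.03), both chosen after their values were seen. Neither call held with only the groups compared, with the replicate block or at equal depth. Among lists the difference between MG and NoTx differed for border macrophages (adjusted p = 7.0e-09, or 0.00015 with an estimated correlation) and blood monocytes (adjusted p = 5.4e-07, or 0.0037 with an estimated correlation). It also differed for bone-marrow-derived macrophages (adjusted p = 1.1e-05, or 0.27 with an estimated correlation), neutrophils (adjusted p = 0.0032, or 0.55 with an estimated correlation), astrocytes (adjusted p = 0.0032, or 0.51 with an estimated correlation), oxidative phosphorylation (adjusted p = 0.0034, or 0.76 with an estimated correlation) and glycolysis (adjusted p = 0.0049, or 0.55 with an estimated correlation). No member of these lists passed.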

How the results depend on the processing

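GC-content correction, thinning and leaving out low-complexity libraries were chosen after the libraries had been seen. Of 198 alternative counts of calls, 106 stayed within 1.5 times the count first reported and 92 did not. Of the 111 calls printed for genes, 108 held with DESeq2, 100 with limma-voom, 110 with RLE scaling, 101 without the filter, 87 with only the groups compared, 93 with the replicate block, 109 after GC-content correction and 98 after thinning. No direction was reversed (0). Of 99 list results 36 held with an estimated correlation, 79 with the replicate block and 88 after GC-content correction. Comparisons below are MLC against MG, MG against NoTx and MLC against NoTx after saline and after seizure, seizure against saline in each kind of cell, and 2 interactions.

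The counts first reported were 299 in MLC against MG after saline, 10 in MG against NoTx after saline, 237 in MLC against NoTx after saline, 1109 in MLC against MG after seizure, 14 in MG against NoTx after seizure, 1162 in MLC against NoTx after seizure, 7 in seizure against saline in MG, 0 in seizure against saline in MLC, 20 in seizure against saline in NoTx, 0 in the interaction of MLC and MG and 2 in the interaction of MG and NoTx. DESeq2 called 660 in MLC against MG after saline, 104 in MG against NoTx after saline, 661 in MLC against NoTx after saline, 2447 in MLC against MG after seizure, 627 in MG against NoTx after seizure, 2748 in MLC against NoTx after seizure, 274 in seizure against saline in MG, 130 in seizure against saline in MLC, 218 in seizure against saline in NoTx, 143 in the interaction of MLC and MG and 189 in the interaction of MG and NoTx. Limma-voom called 1698 in MLC against MG after saline, 439 in MG against NoTx after saline, 1551 in MLC against NoTx after saline, 24 in MG against NoTx after seizure, 260 in seizure against saline in MG, 103 in seizure against saline in MLC, 90 in seizure against saline in NoTx, 8 in the interaction of MLC and MG and 27 in the interaction of MG and NoTx. Without the low-count filter there were 18 in MG against NoTx after saline, 23 in MG against NoTx after seizure, 16 in seizure against saline in MG, 6 in seizure against saline in MLC and 4 in the interaction of MG and NoTx. With only the groups compared there were 872 in MLC against MG after saline, 2 in MG against NoTx after saline, 499 in MLC against NoTx after saline, 502 in MLC against MG after seizure, 0 in MG against NoTx after seizure, 606 in MLC against NoTx after seizure, 0 in seizure against saline in MG, 0 in seizure against saline in NoTx and 0 in the interaction of MG and NoTx. With the replicate block there were 3 in MG against NoTx after saline, 704 in MLC against MG after seizure, 0 in MG against NoTx after seizure, 687 in MLC against NoTx after seizure, 7 in seizure against saline in NoTx and 0 in the interaction of MG and NoTx. With the library code as a block there were 1571 in MLC against MG after seizure and 9 in MG against NoTx after seizure. Without the 2 libraries coded 11b there were 1 in seizure against saline in MLC. After GC-content correction there were 3 in seizure against saline in MG and 1 in the interaction of MG and NoTx. Without the low-complexity libraries there were 617 in MLC against MG after seizure, 29 in MG against NoTx after seizure, 0 in seizure against saline in MG and 5 in the interaction of MG and NoTx. At equal depth there were 6 in MG against NoTx after seizure, 0 in seizure against saline in MG, 8 in seizure against saline in NoTx and 0 in the interaction of MG and NoTx. Leaving out each library gave from 180 (without MG saline replicate 1) to 218 (without MLC saline replicate 3) in MLC against MG after saline, 1 (without NoTx saline replicate 2) to 18 (without NoTx saline replicate 1) in MG against NoTx after saline, 80 (without NoTx saline replicate 2) to 147 (without MLC saline replicate 1) in MLC against NoTx after saline, 776 (without MG seizure replicate 3) to 1112 (without MLC seizure replicate 2) in MLC against MG after seizure, 5 (without MG seizure replicate 3) to 38 (without MG seizure replicate 2) in MG against NoTx after seizure. It gave from 707 (without NoTx seizure replicate 2) to 1189 (without MLC seizure replicate 2) in MLC against NoTx after seizure, 0 (without MG seizure replicate 4) to 13 (without MG seizure replicate 1) in seizure against saline in MG, 0 (without MLC saline replicate 1) to 1 (without MLC seizure replicate 3) in seizure against saline in MLC, 4 (without NoTx seizure replicate 1) to 19 (without NoTx saline replicate 1) in seizure against saline in NoTx, 0 (without MG saline replicate 2) to 7 (without MG seizure replicate 2) in the interaction of MG and NoTx, and 0 in all 16 fits of the interaction of MLC and MG. Fits without a NoTx saline library leave 1 library in that group, whose spread then comes from the other groups. The replicate numbers were not shown to pair samples, so the replicate block is an alternative only.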

Other observations

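The tests of causes in this section were chosen after the result had been seen. A family of near-identical predicted genes on chromosome 14, with Gm3264 as a member, was almost silent in MLC and was chosen after its values were seen. Of 106 annotated members 52 were tested. The summed level of these was 336 ± 52.6 CPM in MG (n = 3), 473 ± 41.4 in NoTx (n = 2) and 7.28 ± 4.21 in MLC (n = 3) after saline. After seizure it was 344 ± 109 in MG (n = 4), 395 ± 95.7 in NoTx (n = 3) and 8.45 ± 8.93 in MLC (n = 6). Of 52 tested members 17 were lower in MLC than in MG after saline and 29 after seizure. No p is given for the sum, since the family was chosen for being low in MLC. The family was low in transplanted cells of monocyte origin and not in transplanted microglia.

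Members shared a median of 89.9% of their 50-base sequences, so reads may be placed among copies by chance. Placement among the tested members leaves their sum unchanged, and this sum was 46.2 times higher in MG than in MLC after saline. Reads placed on annotated members that were not tested are outside the sum. A variant of the donor line might lower the family. MG and MLC donors had the same genotype label, and the lowest MG library exceeded the highest MLC library 10.3 times. The family was chosen for being low in MLC, so this outcome was known in advance and decides nothing about a variant. All 9 MLC libraries were low (2.29 to 25.9 CPM), so a variant of some MLC donors alone would not give this pattern. Whether the donors of every MLC library carried such a variant stays open. Without the family 282 and 1080 genes remained called in MLC against MG.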
